A study of Ciona robusta with 6 samples.

How the data were processed

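RNA was measured in 6 libraries from Ciona robusta, a sea squirt used as a simple chordate model, at 20 h after fertilization. Per the labels' protocols, embryos were dissociated, 1000 cells were sorted into lysis buffer for each sample, and cDNA was made by template switching from 250 to 2000 pg of total RNA. Sequencing libraries were then prepared and barcoded with a low-input kit. Which marker the sort used is not given in the sources used here.

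The authors deposited 1 table of raw read counts, whole numbers per gene model, with no normalization. Per the submitters' processing notes, STAR 2.7.0a, featureCounts from Subread, and DESeq2 were used. The version of featureCounts, the strand setting, the treatment of reads that match several places, and the genome build are not given in the sources used here. The table lists 17822 gene models under KY2019 identifiers, 16396 of them on 14 numbered chromosomes and 1426 on unassigned contigs. No row lacked a gene model, and 557 models had no count in any library. The table's columns were matched to samples through the sample titles, and 0 columns were left without a sample.

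The deposited table does not pair its identifiers with gene names. None of them (0) matched the 21486 genes of the RefSeq table for assembly ASM961781v2, in which 21447 genes carry only a LOC or tRNA symbol. The edited gene Rnf149, the gene Tyr named in the control titles, and the 27 gene lists fixed before the data were examined (heart and pharyngeal muscle regulators, sarcomere, MAPK, p53, stress and other cell types, for example) were therefore not analysed here. A check of the labels through the edited gene's own count was not made. Gene models are given by identifier, and the chromosome is read from the identifier. No start or end coordinates were used.

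Total counts ranged from 18127682 to 22115917 per library. With 3 libraries per group, the spread between libraries and not counting error limited the precision of abundant models. Nothing in the labels says that replicates came from separate embryo pools, so p-values measure the spread between these samples, which may be technical.

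Counts were analysed in R 4.3.3 with edgeR 4.0.16. Models were kept by filterByExpr with the group factor, libraries were scaled by TMM, and the 2 groups were compared with glmQLFit (robust, edgeR 4 deviances) and a 2-sided glmQLFTest. Benjamini-Hochberg adjustment ran over all models tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values, counts scaled to a common library total, use TMM-scaled totals. Log2 CPM for correlations and principal components used a prior count of 2.

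The rule for naming models, fixed before the data were examined, took those past the threshold with non-overlapping groups and a mean count of at least 20, by size of fold change, and at most 2 in each direction if identifiers carried no names. Chromosomes were compared with 2-sided Fisher's exact tests of called against tested models. Alternatives used other size factors, no filter, a strict filter (at least 50 counts in 3 libraries), the non-robust and legacy quasi-likelihood fits, limma-voom (limma 3.58.1) with and without sample weights, DESeq2 1.42.0, thinning to the smallest library, the replicate number as a block, other thresholds, and the removal of each library in turn.

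The scripts were tested on simulated data: 5 negative binomial data sets of 13789 models with the means, library sizes and dispersions of this comparison, each with 200 models changed. The edgeR test recovered 14.6% of models changed 2-fold and 53.2% of those changed 4-fold, and 10.8% of its calls were false. That share, 8.2 false calls per simulation, is above the 5% that the threshold aims at. DESeq2 recovered 32% and 69.8%, and 35.2% of its calls were false.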

Results

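Gene expression was profiled in cells sorted from Ciona robusta embryos at 20 h after fertilization. The design compared CRISPR/Cas9 mutagenesis of Rnf149 with a control in the cardiopharyngeal lineage, which gives rise to the heart and the pharyngeal (siphon) muscles. Rnf149 belongs to the RING finger proteins, a family that includes many E3 ubiquitin ligases. The control libraries carry Tyr in their titles. Each group had 3 libraries.

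The control libraries held 20771781, 21875639 and 20820454 counts for replicates 1, 2 and 3, and the CRISPR libraries 18127682, 22115917 and 19350064. Between 15196 and 16271 gene models had at least 1 count. Models on unassigned contigs took 0.903% of the counts in CRISPR replicate 1 and between 0.717% and 0.788% in the other libraries. The 10 most counted models took between 8.62% and 10.6% of each library.

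Correlations within and between the groups overlapped. Pearson's r of log2 CPM across genes ran from 0.880 to 0.932 among controls, from 0.930 to 0.955 among CRISPR libraries, and from 0.884 to 0.950 between the groups. Genes are not independent replicates, so these values are descriptions. The first principal component held 36.7% of the variance and placed control replicate 3 with CRISPR replicates 1 and 2, on the opposite side from control replicates 1 and 2 and CRISPR replicate 3. The second component held 27.3%, and all 3 CRISPR libraries lay above the controls on it.

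**Figure D1:**
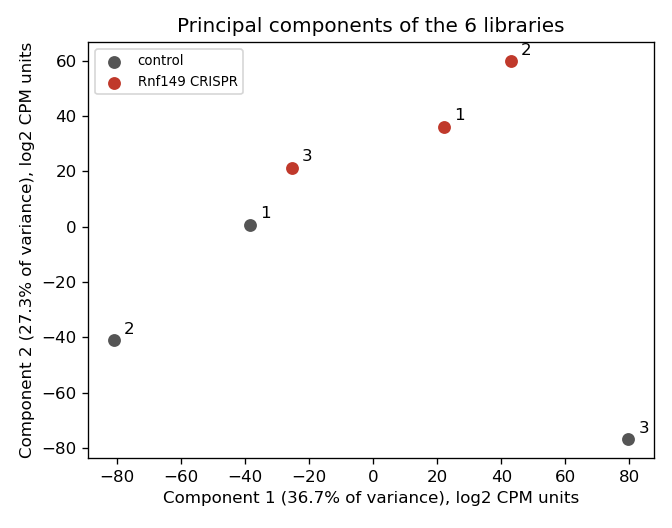
Principal components 1 (x, 36.7% of variance) and 2 (y, 27.3%) of log2 CPM, 1 point per library, grey for control and red for Rnf149 CRISPR, numbered by replicate. Component 1 mixes the groups, while on component 2 the CRISPR libraries lie at 21.3 to 59.8 and the controls at 0.681 or lower.

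The comparison of CRISPR with control libraries asked which transcripts differ in the lineage after mutagenesis of Rnf149. Of 13789 gene models tested, 3 were higher and 4 were lower in the CRISPR libraries at an edgeR adjusted p under 0.05. Among these 4 lower models, KY.Chr2.519, on chromosome 2, fell most, by 4.55-fold. Its level was 777.5 ± 91.7 CPM in controls and 170.7 ± 22.7 CPM in CRISPR libraries (SD, n = 3 each). KY.Chr6.454, on chromosome 6, fell 3.07-fold, from 162 ± 22.2 to 52.8 ± 11.1 CPM. KY.Chr14.1110, on chromosome 14, rose 2.93-fold, from 159.5 ± 18.4 to 467.2 ± 103.8 CPM. KY.Chr1.1687, on chromosome 1, rose 2.33-fold, from 347.2 ± 19.1 to 810.6 ± 80.0 CPM.

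On the log2 scale, KY.Chr2.519 changed by -2.19 (SE 0.14, edgeR adjusted p = 0.00232) and KY.Chr6.454 by -1.62 (SE 0.19, edgeR adjusted p = 0.0446). KY.Chr1.1687 changed by 1.22 (SE 0.11, edgeR adjusted p = 0.0212) and KY.Chr14.1110 by 1.55 (SE 0.18, edgeR adjusted p = 0.0428). KY.Chr6.454 and KY.Chr14.1110 each passed the threshold in 9 of 19 alternative fits, with adjusted p up to 0.309 and 0.277, and both missed it with limma-voom and with the non-robust and legacy edgeR fits. KY.Chr1.1687 passed in 14 and KY.Chr2.519 in 18 of the 19. For all 4, the passes include the fits with other size factors or filters and the thinned fit, which differ little from the main fit. In KY.Chr2.519 the 3 CRISPR libraries had 3625, 3476 and 3062 counts against 15463, 14933 and 18616 in the controls. No other tested model had log2 CPM within 0.3 of any of these 4 in all 6 libraries (0 models each), so none shared its profile with a near-identical copy at that tolerance. The remaining 3 calls were a model on chromosome 1 that rose 2-fold and models on chromosomes 3 and 5 that fell 2.44-fold and 2.22-fold.

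**Figure D2:**
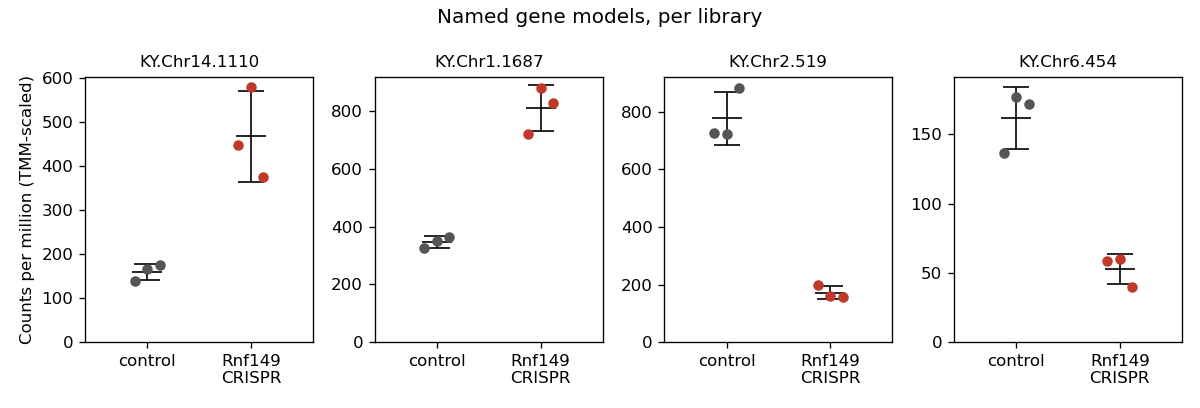
CPM (y, from 0) of KY.Chr14.1110, KY.Chr1.1687, KY.Chr2.519 and KY.Chr6.454 in each control (grey) and Rnf149 CRISPR (red) library, with the mean and SD (black, n = 3). The groups do not overlap in any of the 4 models, and KY.Chr2.519 lies at 724 to 883 CPM in controls against 155 to 197 CPM in CRISPR libraries.

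All 7 called models were abundant. Their mean counts ran from 2227 to 19718 per library, and the least abundant of them stood at the 84.4th percentile of tested models by mean CPM. Their median SE was 0.14 on the log2 scale, against 0.32 for all tested models. By the fitted fold change, a further 853 models were more than 2-fold higher and 1076 more than 2-fold lower without passing the threshold. Of these 1929 models, 1823 were less abundant than every called model, and 802 had an unadjusted p under 0.05. The lower ones include models that differed at least 16-fold among the control libraries, for example KY.Chr1.2555 (log2 fold change -2.63). In all, 1591 models (11.5%) had an unadjusted p under 0.05 in the edgeR test, against 689 expected by chance. The 3 libraries of one group all lay above the 3 of the other in 2216 models (16.1%; chance gives 10%), with 1204 higher and 1012 lower in CRISPR libraries. Neither excess is particular to the guide. A split of control replicates 1 and 2 and CRISPR replicate 3 against the rest gave 1603 models and 16.0%. The number of calls rested on single libraries: it was 60 without CRISPR replicate 3, 12 without control replicate 3, 6 without control replicate 1, and 1 without control replicate 2, CRISPR replicate 1 or CRISPR replicate 2. The 7 models were all among the 60, but 4 of them were among the 12, 2 among the 6, and 1 in each of the last 3 fits. DESeq2, the tool in the submitters' processing notes, called 549 models, 337 higher and 212 lower, which included the 7. In the simulated data, 10.8% of edgeR calls and 35.2% of DESeq2 calls were false.

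**Figure D3:**
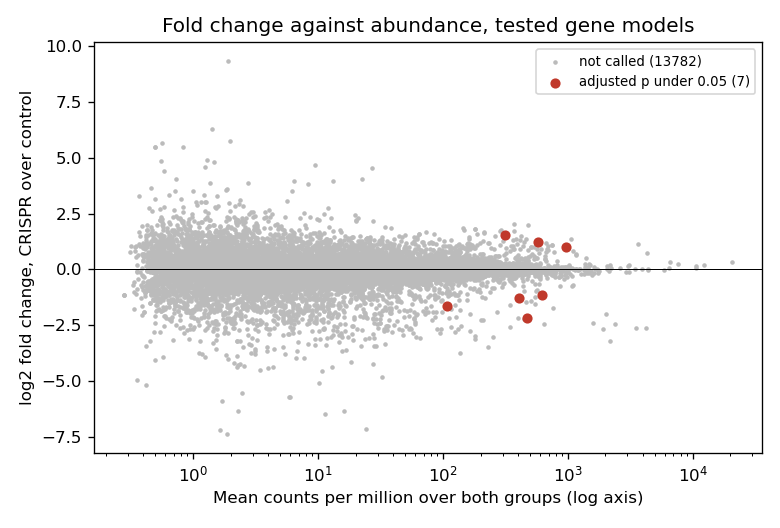
Log2 fold change of CRISPR over control (y) against mean CPM (x, log axis), 1 point per tested model, with the 7 called models in red and the other 13782 in grey. The called models lie among the abundant ones, where the scatter of fold changes is narrow.

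The chromosomal position of changed models was compared next. The lesion is local, but the position of Rnf149 was not known here, so no chromosome can be linked to it. The 7 called models lay on chromosomes 1 (2 models), 2, 3, 5, 6 and 14, and no chromosome passed the test (0 chromosomes, Fisher's exact test, adjusted p = 1 in each, 0 at an unadjusted p under 0.05). With the looser set of 557 models at an unadjusted edgeR p under 0.01, 349 higher and 208 lower, chromosome 9 held 59 of its 933 tested models (6.32% against 4.04% over all, odds ratio 1.68, Fisher's exact adjusted p = 0.00807). Of these 59, 41 were higher and 18 lower in CRISPR libraries. Chromosome 1 held 87 of 1720 (5.06%, adjusted p = 0.194) and chromosome 10 held 25 of 911 (2.74%, adjusted p = 0.222), and no chromosome but 9 passed. Fisher's test takes models as independent, which consecutive models were not.

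Consecutively numbered models tended to change together. Of 10709 pairs of consecutive tested models, 44 had both members at an unadjusted p under 0.01 in the same direction, 31 pairs higher and 13 lower, and 8 had members in opposite directions. Shuffling the models over positions gave 9.26 same-direction pairs on average and at most 22 in 10000 shuffles (1-sided permutation p = 1e-04, the smallest that these shuffles can give). The log2 fold changes of consecutive models correlated at r = 0.157 (Spearman's rho = 0.160) across pairs, which are not independent replicates. Shuffles reached at most 0.041 in size (2-sided permutation p = 1e-04, again the smallest possible). None of the 44 pairs (0) had near-identical counts, that is log2 CPM within 0.3 in every library, and 50 of all 10709 pairs did.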

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

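The count of 7 changed models stayed at 7, and held the same 7 models, with RLE, upper-quartile or no composition factors, with no filter or the strict filter, and after thinning to the smallest library. TMM factors lay between 0.944 and 1.03 and the 7 models were abundant, so these settings could change little. The count was 3 with limma-voom, 3 with sample quality weights, 3 with the legacy fit, 2 without robust estimation, 66 at an adjusted p under 0.1, and 6 when a fold over 2 was also required. It was 549 with DESeq2 and, in a fit added after the data were seen, 509 with DESeq2 and a replicate block. Leaving out 1 library gave 1 to 60 calls, with the highest count without CRISPR replicate 3. These fits leave 2 libraries in 1 group. The counts gave no sign that replicate numbers pair the libraries. Deviations from the group means correlated at -0.033, -0.123 and -0.270 for numbers 1, 2 and 3, and 0 of 6 libraries matched best with their own number. Other variation across the groups could hide a pairing, so this does not exclude one. With the replicate number as a block, edgeR called 0 models, with 1274 at an unadjusted p under 0.05. KY.Chr2.519 kept its direction in all 19 alternative fits and passed the threshold in 18, with the exception of the replicate block (adjusted p = 0.0721). The other 3 named models also kept their direction in all of them. The chromosome comparison gave 0 chromosomes past the threshold with the 7 calls and 1, chromosome 9, with the 557 models at an unadjusted p under 0.01. The cause of these differences was not tested. In simulated data of this depth and spread, most models changed 2-fold were missed, so models not called here are not shown to be unchanged. The alternatives for the edited gene and for the fixed gene lists were not run, since no identifier was matched to a name.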

Other observations

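Every test here was chosen after the pattern it bears on, or a closely related one, had been seen. Only for library depth was the expected outcome set before the test's own result was known.

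Some models varied widely among the control libraries. Of 9929 models with a mean control count of at least 100, 289 differed at least 16-fold between the highest and the lowest control library (0.1 CPM added). The same fold and minimum count among the CRISPR libraries gave 39 models. Of the 289, 237 were highest in control replicate 2, 36 in replicate 1 and 16 in replicate 3. The 237 models together took 10% of the counts in control replicate 2, 3.23% in replicate 1 and 0.246% in replicate 3. In the CRISPR libraries they took 0.683%, 0.253% and 1.81% of the counts for replicates 1, 2 and 3. Among the CRISPR libraries, 189 of the 237 were highest in replicate 3. KY.Chr1.2555, chosen after its values were seen as the most abundant of the set, had 127167, 319620 and 5390 counts in the 3 controls and 13538, 6290 and 48759 in the CRISPR libraries. It had an edgeR adjusted p of 0.614. None of the 289 (0) was among the 7 edgeR calls, and 8 were among the 549 of DESeq2. A wide spread within the controls works against a call, so this does not show the calls to be free of this variation.

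The pattern may reflect RNA of other cells taken along in the sort at different shares, as a hypothesis. One outside source would make such models peak in the same control library. Of the 289, 82% did, which lies between the 90% set for and the 75% set against it, so this share decides nothing. The 16 models highest in control replicate 3, picked by that peak, took 0.2% of its counts and 0.0451% in replicate 2. The 237 took their smallest control share in replicate 3. These values argue against the source of the 237 for those 16 models. A source with 1 fixed profile would give the models that peaked in control replicate 2 one ratio of control 1 to CRISPR 3. Of the 237 models, 216 lay above the mean of control 3, CRISPR 1 and CRISPR 2 in both libraries of the ratio. The rest were left out, though a model without an excess in both goes against a fixed profile. With that mean subtracted, 60.6% of the 216 models lay within 1 log2 unit of the median ratio. Without subtraction, 73.1% of the same models did. Both shares lie under the 75% set against a fixed profile. Subtraction adds spread, and the plain ratio keeps each model's baseline, so neither share excludes one source. Among the 93 models at least 4 times the subtracted mean in both libraries, 75.3% lay within 1 log2 unit of their median without subtraction. These models were kept for high values in control 1 and CRISPR 3, which form the ratio, so their share decides nothing. Several sources, a difference in embryo stage between collections, and biological variation between embryo pools were not tested. The labels give no batch, and no marker of a cell type was matched to an identifier.

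The 10 splits of the 6 libraries into groups of 3 bear on how far the calls follow the guide. The real grouping gave 7 edgeR calls and the highest other split 0. It was 1 of 10 splits with as many, and 10 splits are too few for a share under 0.05. By DESeq2 the real grouping gave 549 calls, again 1 of 10, and the highest other split gave 505. That split set control replicates 1 and 2 and CRISPR replicate 3 against the rest, and it had 1603 models at an unadjusted edgeR p under 0.05 against 1591 for the real one. It also had 16.0% of models with non-overlapping groups against 16.1%. On chromosome 9 it had 3.75% of models at an unadjusted p under 0.01 against 3.84% over all, where the real grouping had 6.32% against 4.04%. This points to a structure of the samples that crosses the groups. Library totals did not separate the sides of that split. Control replicates 1 and 2 and CRISPR replicate 3 held 20771781, 21875639 and 19350064 counts. Control replicate 3 and CRISPR replicates 1 and 2 held 20820454, 18127682 and 22115917. After thinning every library to the smallest total, that split still gave 492 DESeq2 calls. With totals this alike on both sides, thinning could change little, so this count decides nothing about depth. The labels give no batch that follows that split.

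The shared movement of consecutive models was examined for an origin in the counting. Without the near-identical pairs, 50 of 10709, the correlation was 0.155, so reads shared between such copies did not account for it. Neighbouring models that share part of their reads at different count levels stayed in this correlation. It was also present where no guide differed: the log2 CPM difference between control replicates 2 and 1 correlated at 0.128 between consecutive models, and that between replicates 3 and 1 at 0.117. The 9 other splits of the libraries gave 0.106 to 0.175, and the highest, control replicates 1 and 2 with CRISPR replicate 3, exceeded the 0.157 of the real grouping. These splits keep part of the difference between the guides, so only the 2 control differences, which share replicate 1, are free of it. By those, a response to the Rnf149 guide alone is unlikely as the source of the correlation. The 44 same-direction pairs were not counted between controls. Shared transcription units or regulatory regions, and reads that overlap neighbouring models, were not tested, since coordinates and strand settings were not used.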
